A study of Mus musculus with 6 samples.

How the data were processed

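Total RNA was measured by RNA sequencing in 6 samples of mouse bone marrow-derived MSCs, 3 of them unstimulated (Control) and 3 given TNF-α (TNF) at 10 ng/mL over 24 h. Cells were grown in α-MEM with 15% fetal bovine serum. Per the labels, RNA was taken with a column kit with DNase treatment and libraries were made with the SMART-Seq Stranded Kit. The authors processed the reads with Trim Galore, STAR, StringTie and Salmon and used genome build GRCm39, with no versions or settings stated.

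The authors deposited 2 files per library. One holds expected counts per gene, deposited as whole numbers and with no gene column. Its title line calls the values normalized and its column name calls them raw. Library totals, upper quartiles and size factors all differ between libraries, so no scaling to depth is visible in these values, and they were used as counts. The other deposited file holds TPM with gene symbols and identifiers. Count lines were paired with TPM lines by position within each library. This pairing was checked: the 260 zeros of the count files fell on the 260 zeros of the TPM files, and the median over genes of the SD over libraries of log2(count/TPM) was 0.027, against 0.343 with the lines moved by 1. All 15634 listed genes had a count of at least 10 in at least 3 libraries, so genes under this minimum were not available. 11 symbols were given to more than 1 gene, and 11 genes had no symbol. Reference annotation for the build named by the authors was not at hand, so no coordinates are given.

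Total counts ranged from 45629973 to 77142418 per library. Counts were fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM factors, glmQLFit and glmQLFTest, group as the only term). The test is two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Printed CPM values use the TMM factors, and SDs are over the 3 libraries of a group. The SE of a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F. It is therefore approximate, above all for genes with few counts in 1 group. The biological coefficient of variation was 0.132. Principal components were taken from log2 CPM with a prior count of 2. For genes with 9 or fewer counts over the 3 libraries of 1 group, the ratio of summed counts is given with an exact (Clopper-Pearson) 95% interval, which covers counting error only, since reads amplified by PCR are not independent molecules.

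There were 34 gene lists, fixed before the data were examined, as were the groups, the tests, the alternative settings and the rule for naming genes. Lists with at least 5 tested members, 33 in all, were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with an estimated correlation, and with fry, each adjusted over lists by Benjamini-Hochberg. List medians were also compared with 10000 random lists of genes of like abundance. The rule named, first, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap and whose mean CPM was at least 5 in the higher group, without predicted genes. Second, it named up to 3 called members of each list with the smallest adjusted p. Last, it named a fixed set of 22 genes where measured. Genes named outside this rule, mostly to spell out counts of 5 or fewer, were chosen after their values were seen.

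The procedure was tested on simulated data with the depths and variability of the 6 libraries and known changes. It called 36% of genes changed 1.5-fold, 83.7% of those changed 2-fold and 98% of those changed 4-fold, and 7 of 15179 unchanged genes. Only 49 or 50 tested genes were changed at each fold. When 1 list was raised 1.5-fold, camera called it and 0 of the other 32 lists. Simulated genes were drawn independently of each other, so correlation between genes of a list was not put to the test.

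The alternative settings were other scalings (RLE factors, library totals, TMM factors from uncalled genes), other tools (DESeq2 1.42.0, limma-voom), limma on log2 TPM with a pseudocount of 1 or 0.1 or with genes of at least 1 TPM, other count filters, stricter thresholds, the replicate number as a block, and leaving out each library. Leaving out Control library 2 and TNF library 2 together, and adding the log2 share of 18S reads as a covariate, were chosen after seeing the data. Repeats without 1 library leave 2 libraries in that group.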

Results

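RNA was sequenced from bone marrow-derived mesenchymal stem cells (MSCs, the adherent stromal cells that can give rise to bone, fat and cartilage cells) of wild-type C57BL/6J mice. The Control group held 3 libraries of unstimulated cells. The TNF group held 3 libraries of cells given 10 ng/mL of TNF-α, an inflammatory cytokine, for 24 h. Total counts were 55969477, 77142418 and 54141846 in Control libraries 1, 2 and 3, and 49119984, 45629973 and 55149746 in TNF libraries 1, 2 and 3. Of the 15634 genes listed, 15547 had enough counts to be tested. The labels do not say whether replicates came from separate cultures or animals, so each p-value measures only the spread between these samples. Gene values below are mean CPM (counts scaled to library size) ± SD with n = 3 libraries in each group, Control first unless stated.

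The first principal component of log2 CPM held 72.3% of the variance, and the 3 TNF libraries lay apart from the 3 Control libraries on it. The second component held 12% and spread the libraries within both groups. Reads of 18S ribosomal RNA (Rn18s-rs5) made up 2.65%, 1.13% and 3.55% of the counts in Control libraries 1, 2 and 3, and 3.25%, 19.4% and 1.11% in TNF libraries 1, 2 and 3. Protein-coding genes held 77.5% of the counts in TNF library 2 and between 94.1% and 96.8% in the other libraries. Mitochondrially encoded mRNAs held 4.45% of the counts in Control library 2 and between 1.59% and 2.16% in the others.

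**Figure D1:**
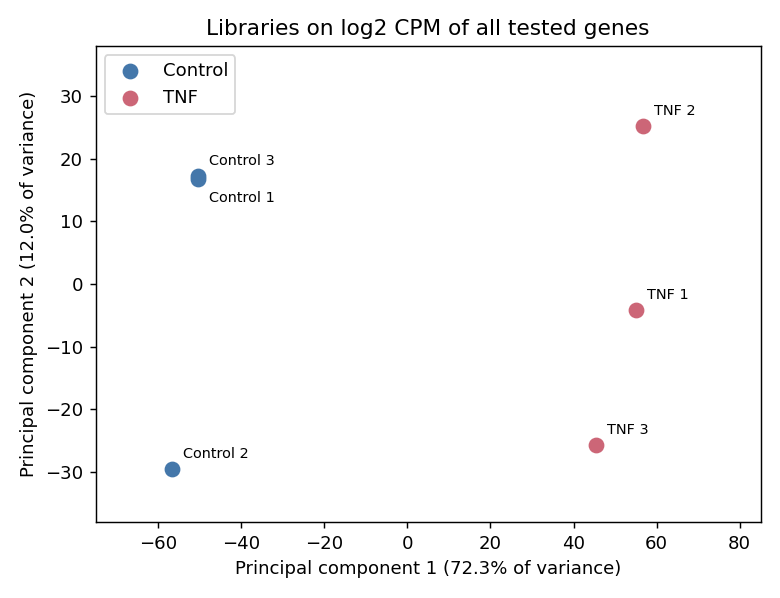
Positions of the 6 libraries on principal components 1 and 2 of log2 CPM of 15547 genes, with 1 point per library coloured by group. The groups separate on component 1 (72.3% of the variance), while component 2 (12%) separates libraries of the same group.

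The comparison of TNF with Control asks which transcripts differ in MSC cultures after stimulation with TNF-α. The series is about macrophages, MSCs and TNF-α in tooth extraction. Bulk RNA does not tell transcripts of MSCs from those of macrophages. Macrophage markers had reads in the Control libraries too, with Cybb at 82.2 ± 18.5 and Cx3cr1 at 25.3 ± 1.11 CPM. The cultures were therefore not shown to hold MSCs alone. Of cytokines and chemokines 24 of 29 tested rose and 2 fell. Ccl2, which attracts monocytes, rose from 19.4 ± 3.29 to 2216 ± 282 CPM, and Ccl5, which attracts T cells and monocytes, from 1.88 ± 1.04 to 877 ± 74.3 CPM (n = 3 each). Of interferon-stimulated genes 48 of 50 tested rose, and of antigen presentation genes 21 of 22. Camera called the interferon-stimulated list at its preset correlation, while an estimated correlation gave adjusted p = 0.0518. Nos2, the inducible nitric oxide synthase, rose from 0.301 ± 0.312 to 351 ± 99.3 CPM. Of osteoblast genes 20 of 30 fell and 3 rose (called by camera at the preset correlation, adjusted p = 0.0733 with an estimated one). Sp7, a transcription factor osteoblasts require, fell from 8.26 ± 0.851 to 0.535 ± 0.0854 CPM. Of proliferation genes 41 of 45 fell (called by camera at the preset correlation, adjusted p = 0.107 with an estimated one).

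edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 5039 genes (32.4% of those tested), 2489 higher and 2550 lower in TNF. A change of at least 2-fold was fitted for 903 of the higher and 812 of the lower genes, and of at least 4-fold for 410 and 180. The median absolute log2 fold change of called genes was 0.72. In 7578 of the 15547 tested genes the 3 values of one group did not overlap the 3 of the other, which 10% of genes would show by chance. Scaling by library totals in place of TMM factors called 1612 higher and 2571 lower, so 38.5% of its calls were higher against 49.4% with TMM. Leaving out 1 library at a time, 1636 of the higher and 1600 of the lower genes were called in all 6 repeats, and 0 called genes changed sign.

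Of the genes with the largest rises, 6 had enough Control counts for a fitted log2 fold change: Nos2 (10.07 ± 0.52 SE), Ccl5 (8.84 ± 0.40), Saa3 (8.61 ± 0.34), Cxcl10 (7.99 ± 0.29), Cxcl9 (7.36 ± 0.40) and Gbp5 (7.33 ± 0.29). Saa3, an acute-phase serum amyloid, rose from 3.01 ± 1.31 to 1191 ± 114 CPM. Cxcl10 and Cxcl9 are ligands of the chemokine receptor CXCR3, and rose from 3.21 ± 1.16 to 821 ± 101 CPM and from 0.273 ± 0.225 to 48.4 ± 11.9 CPM. Within the Control group, Nos2 and Cxcl9 had 50 and 40 counts in library 2, while libraries 1 and 3 had 7 each of Nos2 and 11 and 6 of Cxcl9. Without Control library 2 the log2 fold changes were 11.48 for Nos2 and 8.35 for Cxcl9. Gbp5, an interferon-inducible GTPase, rose from 2.28 ± 0.995 to 374 ± 16.8 CPM. The other 4 had only 1 to 4 counts in each Control library. Their TNF to Control ratios were 991 for the chemokine Ccl20 (95% counting interval 503 to 2297), 472 for Pglyrp3, a peptidoglycan recognition protein (202 to 1455), 359 for the chemokine Cxcl3 (123 to 1746) and 349 for Heatr9 (119 to 1695). These intervals cover counting error only.

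Among genes that fell, Car3, a carbonic anhydrase abundant in fat and muscle, had the largest fitted change (log2 fold change -5.51 ± 0.16 SE), from 72.7 ± 7.72 to 1.61 ± 0.312 CPM. Mest, an imprinted gene of mesodermal tissue, went from 113 ± 9.25 to 6.53 ± 0.558 CPM. Aspn (asporin), a small leucine-rich matrix protein, fell by 4.22 on the log2 scale, and Gdf10, a BMP-family ligand, by 4.14. The same scale gave Galnt15 (-4.14), Mchr1 (-4.10), Sp7 (-3.93), Megf6 (-3.70), Hpgd, which degrades prostaglandins (-3.68), and Plekhg4 (-3.43). Among these 20 genes with the largest changes the highest adjusted p by edgeR's quasi-likelihood test was 2.93e-06, for Cxcl9.

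**Figure D2:**
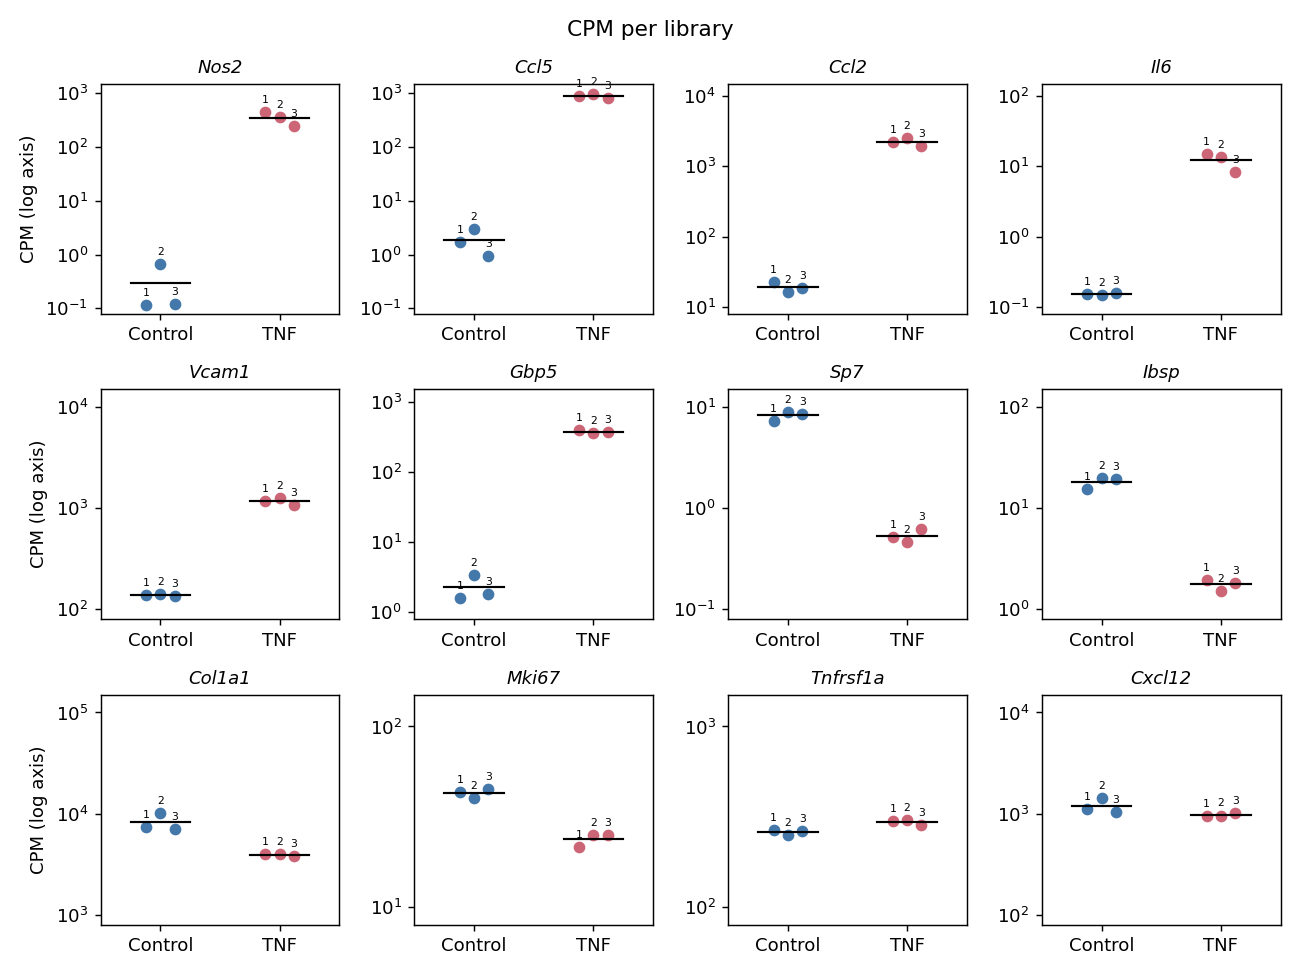
CPM on a log axis in each of the 6 libraries for 12 genes, with 1 point per library, its number above it, and a line at the group mean. All 3 TNF libraries lie above the 3 Control libraries for Nos2, Ccl5, Ccl2, Il6, Vcam1 and Gbp5 and below them for Sp7, Ibsp, Col1a1 and Mki67, while Tnfrsf1a and Cxcl12 were not called.

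Cytokines and chemokines were higher in 24 of 29 tested genes (25 adjusted over the list alone) and lower in 2 (2), with a median log2 fold change of 3.66. Besides those above, Il6, an inflammatory cytokine, rose from 0.152 ± 0.00633 to 12.3 ± 3.47 CPM and Cxcl1, a neutrophil attractant, from 2.74 ± 0.798 to 139 ± 44.1 CPM. Csf1, the growth factor of macrophages, rose from 691 ± 10.0 to 2080 ± 61.7 CPM. The genes that fell were Il33 (-3.25) and Cxcl14 (-0.85). Cxcl12, which retains blood stem cells in marrow, had 1188 ± 203 and 973 ± 31.7 CPM and was not called (adjusted p = 0.154), nor were Tslp (0.0710, and 0.0304 without Control library 2) and Il11.

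The NF-kB pathway, through which TNF receptors signal, was higher in 24 of 25 genes (24 adjusted over the list alone), with a median of 1.97 on the log2 scale. Nfkbie, an inhibitor of NF-kB, rose from 12.2 ± 0.642 to 140 ± 1.70 CPM. Traf1, an adaptor of TNF receptors, rose from 0.318 ± 0.0607 to 10.8 ± 0.636 CPM and the kinase Ripk2 from 18.4 ± 1.39 to 144 ± 7.65 CPM. Rel, the remaining member, was not called (adjusted p = 0.332, and 0.0395 without Control library 2). Among TNF and IL-1 receptors and their signalling genes, 13 of 23 were higher (15 adjusted over the list alone) and 1, Il1r1, lower (1), with adjusted p = 0.0518 with an estimated correlation. Tnfrsf9 rose from 2.10 ± 0.528 to 25.7 ± 0.770 CPM, the death receptor Fas from 31.5 ± 2.47 to 155 ± 13.4 CPM, and Tnf itself from 4.16 ± 0.425 to 13.7 ± 3.28 CPM. Tnfrsf1b, the second TNF receptor, went from 85.3 ± 3.63 to 182 ± 10.6 CPM, while Tnfrsf1a, the main one, had 261 ± 9.24 and 296 ± 11 CPM and was not called (adjusted p = 0.135).

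Interferon-stimulated genes were higher in 48 of 50 (48 adjusted over the list alone), with a median log2 fold change of 2.73 and adjusted p = 0.0518 with an estimated correlation. Gbp2 rose from 69.3 ± 9.44 to 1200 ± 74.4 CPM, Gbp6 from 10.7 ± 1.81 to 521 ± 44.8 CPM and Ifi47 from 12.1 ± 0.751 to 90.0 ± 10.4 CPM, all 3 encoding GTPases of cell-autonomous defence. The Gbp genes resemble each other, so the division of reads among them is uncertain. Isg20 and Ifitm2 were not called. Antigen presentation genes were higher in 21 of 22 (21 adjusted over the list alone), and H2-Eb1 was not called. Psmb9, an immunoproteasome subunit, rose from 6.76 ± 0.271 to 36.6 ± 4.56 CPM and Tapbpl from 17.0 ± 1.26 to 57.7 ± 1.81 CPM. H2-Q4 rose from 3.81 ± 0.759 to 124 ± 27.5 CPM, with reads that could be shared among H2-Q genes. Markers of macrophages and monocytes, which can remain in marrow stromal cultures, went both ways in the same libraries, 6 higher and 9 lower of 25, with an upper quartile of 0.24 on the log2 scale.

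In that marker list 6 and 12 members passed when adjusted over the list alone, and camera did not call it (adjusted p = 0.487), while its median lay below those of 10000 random lists of like abundance (adjusted p = 0.000388, from the smallest p they can give). That comparison treats genes as independent, which markers of the same cells need not be. Cybb, a subunit of the phagocyte oxidase, rose from 82.2 ± 18.5 to 394 ± 44.8 CPM and Cd74, the invariant chain of MHC class II, from 1.45 ± 0.536 to 11.1 ± 0.685 CPM, the latter also a member of the antigen presentation list. Cx3cr1 fell from 25.3 ± 1.11 to 6.50 ± 1.12 CPM, and the complement gene C1qc from 167 ± 39.2 to 60.6 ± 6.17 CPM. The list's median log2 fold change was -0.40 with all libraries and -0.18 without Control library 2.

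Immunomodulatory effectors of MSCs were higher in 11 of 18 genes (11 adjusted over the list alone) and lower in 3 (4). The list is named for MSCs, but the cells in which its genes changed were not determined. Ptges, a prostaglandin E synthase, rose from 33.4 ± 0.516 to 194 ± 22.7 CPM and Cd274, the checkpoint ligand PD-L1, from 3.04 ± 0.341 to 26.9 ± 3.22 CPM. Entpd1 (-2.33), Hgf (-0.50) and Stc1 (-0.78) fell. Stc1 was not called without Control 1, Control 3, TNF 1, TNF 2 or TNF 3 (adjusted p up to 0.10). Anti-apoptotic and oxidative stress genes were higher in 12 of 19 (12 adjusted over the list alone) and lower in 1, Birc5 (2), which was 3 without TNF library 3. Sod2, the mitochondrial superoxide dismutase, rose from 54.3 ± 4.30 to 422 ± 16.4 CPM. Bcl2a1d rose from 0.297 ± 0.0610 to 2.76 ± 0.138 CPM, and Bcl2a1a had a ratio of 72.4 (95% counting interval 32.9 to 199), with a fitted log2 fold change of 6.09, which was 7.04 without Control library 1 and 5.41 without Control library 2. Reads of these near-identical Bcl2a1 genes could be split between them.

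Complement and acute-phase genes were higher in 12 of 21 (13 adjusted over the list alone) and lower in 3 (3), with adjusted p = 0.128 with an estimated correlation. Cfb, of the alternative complement pathway, rose from 3.88 ± 1.03 to 236 ± 29.6 CPM, C3, the central complement protein, from 6.13 ± 1.95 to 150 ± 23.2 CPM and haptoglobin (Hp) from 7.80 ± 1.04 to 51.0 ± 2.77 CPM. C1qtnf1 (-0.44) and Cd59a (-0.26) were among those that fell. Without TNF library 1 the lower count was 1 instead of 3, and Cd59a was not called without Control 1, Control 3, TNF 1 or TNF 3 (adjusted p up to 0.122).

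Regulators of osteoclasts, the cells that resorb bone, were higher in 13 of 20 genes (13 adjusted over the list alone) and lower in 5 (5). Several of the higher ones are chemokines and cytokines given above. Tnfrsf11b, the decoy receptor osteoprotegerin, fell from 212 ± 14.6 to 97.3 ± 9.01 CPM, and the other lower genes were Sema3a (-1.13), Wnt5a (-1.01), Efnb2 (-0.90) and Sfrp1 (-0.78). Tnfsf11, which encodes RANKL, was not among the tested genes.

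Osteoblast genes were lower in 20 of 30 (23 adjusted over the list alone) and higher in 3 (3), with a median of -0.96 on the log2 scale and adjusted p = 0.0733 with an estimated correlation. Runx2, the early transcription factor of bone formation, fell from 92.7 ± 6.69 to 49.4 ± 2.99 CPM. Ibsp, a bone matrix sialoprotein, fell from 18.3 ± 2.40 to 1.77 ± 0.238 CPM and Alpl, the mineralising alkaline phosphatase, from 29.0 ± 5.00 to 14.7 ± 2.43 CPM. Dmp1, an osteocyte gene, was 16.5 times higher in Control (95% counting interval 8.20 to 38.9). Bglap, which encodes osteocalcin, had 1.33 ± 0.229 and 0.760 ± 0.284 CPM and was not called (adjusted p = 0.0764), with reads that could be shared with Bglap2. Bmp2, a bone-inducing ligand, rose from 7.10 ± 1.14 to 54.9 ± 7.90 CPM, with smaller rises of Msx2 (0.71) and Atf4 (0.40). Atf4 was not called without TNF library 1 (adjusted p = 0.0561), and the higher count was 5 without Control library 2.

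Chondrocyte genes were lower in 7 of 13 (9 adjusted over the list alone) and higher in 3 (3), with adjusted p = 0.00800 by camera, 0.0603 with a filter at 5 CPM and adjusted p = 0.281 with an estimated correlation; the other camera settings gave 0.00330 to 0.0309. Sox9, the cartilage transcription factor, fell from 24.4 ± 5.67 to 11.1 ± 1.74 CPM, Col11a1 from 114 ± 7.24 to 32.3 ± 1.09 CPM and Hapln1 from 4.54 ± 1.23 to 1.29 ± 0.296 CPM. Prg4 (0.69), Sox5 (0.66) and Sox6 (0.28) rose, and only 1 member did without Control 1, Control 3, TNF 1 or TNF 2. Prg4 was not called without Control 1 or Control 3 (adjusted p up to 0.0587), Sox5 without TNF 1 or TNF 2 (up to 0.0646), and Sox6 without Control 1, Control 3, TNF 1 or TNF 2 (up to 0.129). Adipocyte genes went both ways, 6 higher and 8 lower of 21 (8 and 8 adjusted over the list alone; camera adjusted p = 0.881). Pparg, the main regulator of fat cells, fell from 11.2 ± 1.44 to 5.35 ± 0.536 CPM and Cebpa from 42.1 ± 4.17 to 20.9 ± 2.12 CPM, while Cebpd, which acts early in the same programme, rose from 28.8 ± 2.24 to 133 ± 20.2 CPM. The median of this list was 0.003 and its mean -0.13 on the log2 scale, and the test pointed down.

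Collagens and matrix structure genes were lower in 24 of 49 (28 adjusted over the list alone) and higher in 5 (5), with adjusted p = 0.00570 by camera and adjusted p = 0.813 with an estimated correlation. Col1a1, of the main bone collagen, fell from 8204 ± 1686 to 3938 ± 109 CPM and Ogn, a small leucine-rich protein, from 1432 ± 297 to 162 ± 13.7 CPM. Col5a3 rose from 50.8 ± 0.724 to 304 ± 8.42 CPM and Col18a1 from 11.7 ± 0.233 to 44.9 ± 0.529 CPM, followed by Eln (2.77), P4ha2 (0.37) and Loxl2 (0.36). Without TNF library 1 the counts were 15 lower and 3 higher, and without Control library 2 the higher count was 8. P4ha2 was not called without TNF 1 (adjusted p = 0.0511), nor Loxl2 without Control 1, Control 3, TNF 1 or TNF 2 (up to 0.109). Matrix proteases and their inhibitors were higher in 13 of 34 (16 adjusted over the list alone) and lower in 10 (11), with adjusted p = 0.441 with an estimated correlation. Mmp3 (stromelysin) rose from 26.7 ± 3.05 to 1171 ± 111 CPM, Adamts14 from 12.4 ± 0.435 to 59.5 ± 4.04 CPM and Adamts7 from 8.10 ± 1.03 to 46.5 ± 0.202 CPM. The lower count of this list was 6 without TNF library 1 or TNF library 3.

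Wnt signalling genes were lower in 25 of 38 (25 adjusted over the list alone) and higher in 3 (3), with adjusted p = 0.142 with an estimated correlation. Nkd1, a feedback inhibitor of Wnt, fell from 4.68 ± 0.228 to 0.516 ± 0.104 CPM, the ligand Wnt4 from 22.3 ± 6.31 to 2.69 ± 0.114 CPM and the receptor Fzd5 from 95.1 ± 8.18 to 40.2 ± 2.81 CPM. The list holds inhibitors of Wnt as well as activators. Rspo3 (1.03), Rspo2 (0.79) and Wnt2b (0.81) rose, the last not called without Control 1, Control 2, Control 3, TNF 1 or TNF 2 (adjusted p up to 0.135). TGF-beta and BMP signalling genes went both ways, 9 higher and 16 lower of 37 (9 and 16 adjusted over the list alone; camera adjusted p = 0.973). The median of that list was -0.19 and its mean 0.01 on the log2 scale, and the test pointed up. The receptor Bmpr1b rose from 0.977 ± 0.237 to 8.56 ± 0.393 CPM.

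**Figure D3:**
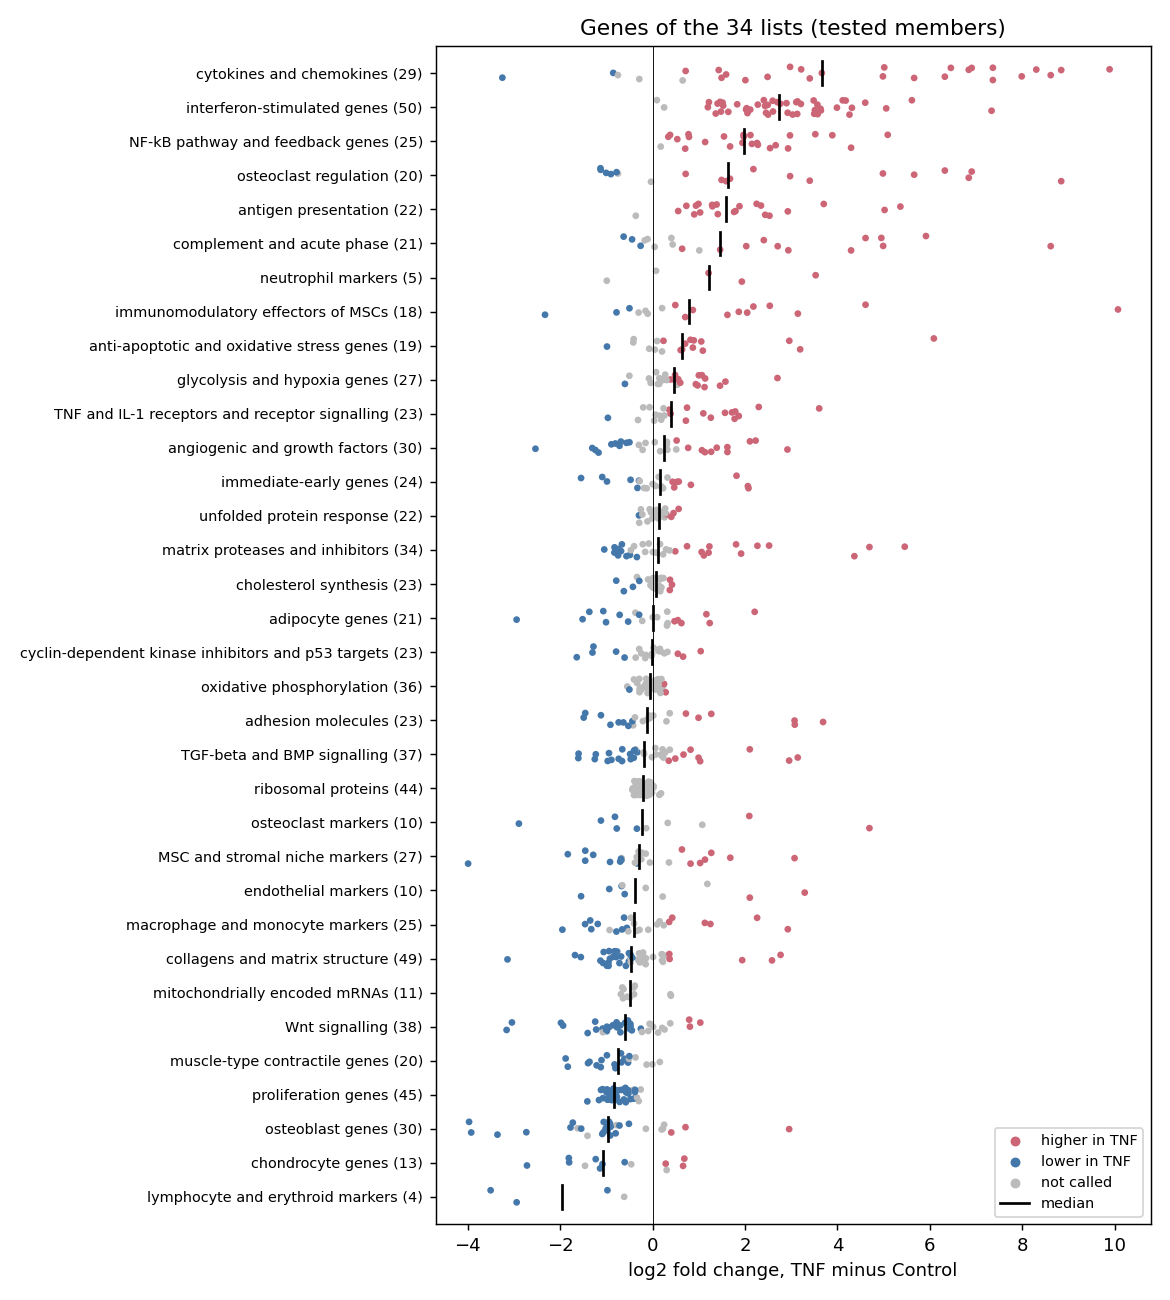
Log2 fold change (TNF minus Control) of each tested member of the 34 gene lists, with 1 point per gene coloured by its call and a line at the median of each list. Cytokines and chemokines have a median of 3.66, interferon-stimulated genes 2.73 and osteoblast genes -0.96.

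Proliferation genes were lower in 41 of 45 (44 adjusted over the list alone), with a median of -0.84 on the log2 scale and adjusted p = 0.107 with an estimated correlation. Mki67, present in cycling cells, fell from 43.0 ± 2.53 to 23.9 ± 2.09 CPM, Cenpf from 20.7 ± 1.18 to 9.84 ± 0.311 CPM and the cyclin Ccna2 from 28.2 ± 1.71 to 14.3 ± 0.477 CPM. Ccne1, Ccnd1, Tyms and Cenpe were not called, the last at adjusted p = 0.0818, and 0.00245 without Control library 2. Contractile genes of the smooth muscle type were lower in 15 of 20 (17 adjusted over the list alone), with adjusted p = 0.0518 with an estimated correlation. Smtn fell from 98.8 ± 3.87 to 45.8 ± 2.13 CPM, Synpo2 from 27.3 ± 1.16 to 11.8 ± 0.498 CPM and the integrin Itga8 from 17.3 ± 3.77 to 4.69 ± 0.195 CPM.

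Adhesion molecules went both ways, 6 higher and 8 lower of 23 (8 and 10 adjusted over the list alone; camera adjusted p = 0.654). Icam1 and Vcam1, which bind leukocyte integrins, rose from 16.5 ± 2.41 to 213 ± 9.20 CPM and from 139 ± 3.95 to 1170 ± 91.7 CPM, and Itga1 fell from 51.0 ± 1.83 to 18.2 ± 1.14 CPM. The median of the list was -0.12 and its mean 0.21 on the log2 scale, and the test pointed up. MSC and stromal niche markers were higher in 7 and lower in 10 of 27 (8 and 12 adjusted over the list alone; camera adjusted p = 0.409). Cd44 rose from 177 ± 7.01 to 428 ± 9.45 CPM and Lepr, a marker of marrow stromal cells, from 0.476 ± 0.197 to 1.55 ± 0.330 CPM, while Mcam (CD146) fell from 29.1 ± 0.904 to 10.6 ± 0.509 CPM. Angiogenic and growth factors were higher in 11 and lower in 10 of 30 (12 and 10 adjusted over the list alone; camera adjusted p = 0.120, 0.0446 with a filter at 5 CPM, and 0.0542 to 0.600 in the other camera settings). Angptl4 rose from 26.0 ± 0.313 to 197 ± 21.6 CPM and the neurotrophic factor Gdnf from 8.35 ± 0.325 to 25.7 ± 1.65 CPM, and Angpt2 fell from 4.12 ± 0.174 to 0.708 ± 0.0766 CPM. Glycolysis and hypoxia genes were higher in 14 of 27 (14 adjusted over the list alone) and lower in 1, Ndrg1 (2), with adjusted p = 0.218 with an estimated correlation. Egln3, an oxygen-sensing hydroxylase, rose from 1.96 ± 0.0809 to 12.7 ± 1.52 CPM and Vegfa, the vessel growth factor, from 52.8 ± 1.44 to 111 ± 8.89 CPM.

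Camera with its preset correlation of 0.01 called 17 of the 33 lists it tested, 11 higher and 6 lower. The 6 lower lists were osteoblast, chondrocyte, collagen and matrix structure, Wnt, contractile and proliferation genes. The same setting called up to 21 lists when libraries of both groups were mixed. Those mixed groups still differ in part by TNF, so the 21 lists are no count of false calls. With an estimated correlation 6 of the 17 held, all higher: cytokines and chemokines, NF-kB, anti-apoptotic and oxidative stress, antigen presentation, immunomodulatory effectors and osteoclast regulation. The remaining higher lists were interferon-stimulated genes, TNF and IL-1 receptors, complement and acute phase, matrix proteases, and glycolysis and hypoxia. Fry, which asks whether a list's genes move on balance one way and compares it with no other genes, called 19 lists.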

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

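Leaving out Control library 2 and TNF library 2 together, the 18S covariate and the counts over splits of the samples were chosen after the results were seen. The counts of 2489 higher and 2550 lower genes stayed within 1.5 times with RLE factors, TMM factors from uncalled genes, DESeq2, limma-voom, no count filter, a filter at 5 CPM and the replicate number as a block. The higher count was 1612 with library totals, 1477 and 1470 with limma on TPM at pseudocounts of 1 and 0.1, and 1356 with genes of at least 1 TPM. Library totals leave out the TMM factors, which were 0.858 in TNF library 2 and 0.980 to 1.06 in the others. Without them the median log2 fold change of all genes was -0.09. TNF library 2 also held the highest 18S share, 19.4%. The TPM fits moved that median to -0.05, -0.07 and -0.06. How far these shifts lowered the counts was not tested. By construction, stricter thresholds called fewer: 1587 higher and 1534 lower at an adjusted p under 0.01, 903 and 812 with a fold of at least 2, and 1585 and 1630 when a fold over 1.2 was tested. Leaving out 1 library gave 1721 to 2413 higher and 1728 to 2382 lower genes, from fewer samples, and 11 to 12 higher and 6 to 7 lower lists. Of the 119 called genes that the naming rule gave, 113 were called in all 6 repeats. Without Control library 2 and TNF library 2 there were 2721 higher and 2518 lower genes, of which 2226 and 2175 were called with all libraries, and 11 higher and 6 lower lists. With the 18S covariate there were 2478 and 2492 (2317 and 2328 shared). Deviations from the group means of libraries with the same replicate number correlated across genes at -0.01, -0.30 and -0.22. Libraries with unlike numbers ran from -0.23 (Control 1 with TNF 3) to 0.36 (Control 2 with TNF 3). The same numbers thus gave no sign of pairing. With 3 libraries in each group, which also differ in 18S share, this check cannot exclude it.

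Against 11 higher and 6 lower lists by camera at the preset correlation, an estimated correlation gave 6 and 0, and a filter at 5 CPM with the preset correlation 13 and 5. Other tests gave 14 and 5 (fry) and 12 and 11 (random lists of like abundance). Random lists called angiogenic factors and neutrophil markers higher and macrophage, MSC, TGF-beta and BMP, ribosomal and mitochondrial lists lower, which camera did not, and did not call the proteases. The random lists compare medians and treat genes as independent, while camera compares means and allows for correlation between genes. Median and mean were 0.12 and 0.64 for the proteases and -0.40 and -0.17 for macrophage markers. Which difference decided each list was not tested. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. All but the real one mix Control and TNF libraries within each group. The TNF difference then widens the spread within these groups, which by itself lowers the calls. Part of it also stays between them, so the lists they call need not be false. These splits are therefore no reference without an effect, and no conclusion is drawn from them. The real split called 5039 genes by edgeR and the highest of the others 0 (up to 413 at an unadjusted p under 0.05), so 1 split of 10 gave as many. For lists at the preset correlation the real split called 17 and the highest of the others 21, and 3 splits of 10 gave as many as the real one. With the estimated correlation these were 6 and 0, and with fry 19 and 0. Ifitm2 was not called with counts (log2 fold change 0.09). In the TPM fits (pseudocounts of 1 and 0.1, genes of at least 1 TPM) it was at -0.002758, -0.002806 and -0.002758, again not called. Those fits also lowered the median of all genes, and whether this accounts for the difference was not tested. Rn18s-rs5 (18S RNA), not called at 1.94, was at -0.1431 without TNF library 2, at 2.464 without TNF library 3, where it passed, and at -0.4608 without Control library 2 and TNF library 2; TNF library 2 held its highest share, 19.4%. Rel, Ifitm2, Tnfrsf1a, Bglap, Tslp, Lyz2, Ccnd1 and Cenpe, not called with all libraries and TMM, passed in at least 1 of the other settings. Depth limits the ratios of genes with few counts in 1 group, and simulated changes of 1.5-fold were called in 36% of genes. The simulation changed far fewer genes than the 5039 called here. The adjusted threshold depends on the share of changed genes, so the 36% does not carry over directly.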

Other observations

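Of the tests of possible explanations below, all were chosen after the results were seen except that of the interferon-stimulated median in Control library 2 (its comparison with other lists came after) and that of component 2 on protein-coding genes, while the lists and their set tests were fixed before the data were examined. The repeat without Control library 2 and TNF library 2 was also chosen afterwards. Genes of oxidative phosphorylation gave 2 higher (Sdhb and Ndufab1) and 1 lower (Ndufa1) of 36, 0 and 0 adjusted over the list alone, and camera adjusted p = 0.619. The higher count was 0 with library totals and with TPM at a pseudocount of 1, and 3 without Control library 2 and TNF library 2. Sdhb and Ndufab1 were not called without Control 1, Control 2, TNF 1 or TNF 3 (adjusted p up to 0.119 and 0.113), nor Ndufa1 without TNF 1 or TNF 2 (up to 0.0736). The lower count was 2 without Control 1 and 5 without TNF 3. In cholesterol synthesis 3 of 23 genes were higher and 4 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.973), with a median of 0.08, a mean of -0.003 and a test pointing up. Msmo1 (0.42) and Sqle (0.38) were among those that rose, and Ebp (-0.79), Pmvk (-0.62), Tm7sf2 (-0.43) and Dhcr7 (-0.29) fell. Of the genes named here only Msmo1 and Ebp were called in all 6 repeats without 1 library: the higher count was 1 without TNF 1, and the lower count 2 without Control 1, Control 2 or Control 3 and 1 without TNF 1 or TNF 2. The higher count of this list was 0 with library totals and 7 without Control library 2 and TNF library 2. The unfolded protein response was higher in 4 of 22 and lower in 1 (3 and 0 adjusted over the list alone; camera adjusted p = 0.506). Its chaperone Hspa5 rose from 530 ± 32.6 to 783 ± 8.07 CPM (SD, n = 3), with Creld2 (0.45), Atf4 (0.40) and Dnajb9 (0.30), and Atf3 (-0.30) fell. The higher count of this list was 0 with library totals, 1 with TPM at a pseudocount of 1 and 7 without Control library 2 and TNF library 2. Without TNF 1 the higher count was 2 (Atf4 at adjusted p = 0.0561), Dnajb9 was not called without any 1 library but Control 2 (up to 0.0911), and Atf3 was called in none of the 6 repeats (up to 0.114). Inhibitors of cyclin-dependent kinases and p53 targets were higher in 3 of 23 (Gadd45b, Mdm2, Cdkn1a) and lower in 5 (Cdkn1c, Cdkn2c, Gadd45g, Cdkn1b, Sesn1), with 3 and 5 adjusted over the list alone and camera adjusted p = 0.409. Cdkn1a was not called without TNF 1 (adjusted p = 0.0610), and the higher count was 5 without TNF 3. Immediate-early genes were higher in 8 and lower in 6 of 24 (8 and 6 adjusted over the list alone; camera adjusted p = 0.120, 0.0280 with a filter at 5 CPM, 0.0480 without TNF 3, and 0.111 to 0.329 in the other camera settings). Junb rose from 64.0 ± 6.80 to 269 ± 30.6 CPM and Egr2 from 7.34 ± 0.269 to 25.9 ± 1.32 CPM, and the lower count was 2 without Control 1 and 3 without TNF 1 or TNF 3.

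Of neutrophil markers, Camp, S100a8 and Mmp8 were higher (3 of 5, 3 adjusted over the list alone, camera adjusted p = 0.149), each under 2 CPM, and Mmp8 was not called without Control 1, Control 3, TNF 1 or TNF 3 (adjusted p up to 0.112). In the lymphocyte and erythroid list, too short for camera, 3 of 4 were lower (3 adjusted over the list alone): Trac, Ighm and Trbc2, the last with a Control to TNF ratio of 11.5 (95% counting interval 5.86 to 25.6) and a fitted log2 fold change of -3.51, which was -5.72 without TNF library 3. Endothelial markers were higher in 2 of 10 (Selp and Flt1) and lower in 4 (Kdr, Stab2, Egfl7, Vwf), with 3 and 4 adjusted over the list alone. Their median was -0.38, their mean 0.22 and the test pointed up (camera adjusted p = 0.732). The lower count was 2 without Control 1, Control 3 or TNF 1, without which Kdr was not called (adjusted p up to 0.0762), and Vwf was called only in the repeat without TNF 2 (otherwise up to 0.0942). Osteoclast markers were higher in 2 of 10 (Mmp9 and Dcstamp, a fusion protein) and lower in 5 (Car2, Itgb3, Atp6v0d2, Tnfrsf11a, Ctsk), with 3 and 5 adjusted over the list alone. Their median was -0.24 and their mean 0.21, camera pointed down (adjusted p = 0.973) and fry up, and Ctsk was not called without Control 1, TNF 1 or TNF 3 (up to 0.0879). Of 44 ribosomal protein genes edgeR called 0, with 1 lower at an unadjusted p under 0.05 and 1 lower by DESeq2; edgeR called 2 lower without TNF library 3 and 1 higher without Control library 2 and TNF library 2. Their median was -0.20 (0.02 without Control library 2 and TNF library 2), and camera gave adjusted p = 0.121 with all libraries, 0.0308 without Control 1 and 0.00524 without TNF 3. Of 11 mitochondrially encoded mRNAs 0 were called by edgeR, DESeq2 or limma-voom and 0 passed unadjusted, with camera adjusted p = 0.504. Their median was -0.49 with all libraries and 0.03 without Control library 2.

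The rise of the interferon-stimulated genes could come from a larger share of macrophages in the TNF libraries, since no sort of the cells is stated. Macrophage markers argue against this: their upper quartile was 0.239 on the log2 scale, below the lower quartile of 2.03 of the interferon-stimulated list, with 0 genes shared by both lists. Their most abundant member, Lyz2, had 1334 CPM in Control and 925 CPM in TNF and was not called. Of the 25 markers 9 were called lower and 6 higher: Cybb, Cd74, Cd14, Msr1, Spi1 and Csf1r. Csf1r was not called without Control 1, Control 3 or TNF 1 (adjusted p up to 0.0971). Markers can also change within a cell, so they do not measure the share of macrophages directly. A few libraries did not carry the rise either, as the lowest median of the list without a library was 2.64. A response of the MSCs, of macrophages already present, or of both stays open, as bulk RNA does not assign these transcripts to cells.

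Nos2 and Cxcl9 were 5.50 and 3.65 times higher in Control library 2 than in the mean of the other Control libraries. Reads carried over from the TNF libraries would give 1 common share of the TNF level, but the excess over 8 other strongly raised genes had a median of 0.0973% and ran from -0.112% for Ccl20 to 0.459% for Gbp5, all below the 0.794% that Cxcl9 needs, which argues against this source for Cxcl9. For Nos2, which needs 0.154%, the genes disagreed. Ccl5 (0.192%), Saa3 (0.188%), Cxcl10 (0.238%) and Gbp5 lay above that share. Ccl20, Pglyrp3, Cxcl3 and Heatr9 lay below it, each resting on 1 or 2 counts in Control library 2. Ccl20 was not raised in that library (4, 1 and 3 counts in Control libraries 1, 2 and 3). Ccl2, outside the 8 genes, was not raised there either (22.9, 16.4 and 18.8 CPM in Control libraries 1, 2 and 3). Carried-over reads therefore stay open as a source of Nos2. A larger share of macrophages as the whole source is argued against by the upper quartile of their markers, 0.629 in log2 difference where Nos2 showed 2.46, though their median was raised by 0.499. A low interferon response in that sample may contribute but was not singled out: the interferon-stimulated list was 0.298 higher by the median (-0.118 between the other Control libraries), its upper quartile of 0.489 also lay below 2.46, and it ranked 7 of 34 lists, behind, among others, macrophage markers, complement (0.499) and mitochondrial mRNAs (1.24).

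Component 2 followed the log2 share of 18S reads over the 6 libraries (Pearson r = 0.830, permutation p = 0.0139, adjusted 0.0222; Spearman rho = 0.886, permutation p = 0.0333, adjusted 0.0667; 2 relations computed), with r = 0.846 without TNF libraries 2 and 3. On protein-coding genes outside mitochondria r was 0.826 (permutation p = 0.0222, adjusted 0.0222; rho = 0.771, permutation p = 0.103, adjusted 0.103) and 0.843 without those libraries. These were 13663 of the 15547 genes, so the repeat could hardly turn out otherwise. It shows that protein-coding genes carry the component too, but does not decide whether ribosomal and small structural RNA was its source. Within a group there are only 3 libraries, too few for a correlation. RNA quality or library preparation may underlie the component, but neither was measured, and no biological explanation was tested.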
